A study of Mus musculus with 54 samples.

How the data were processed

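RNA sequencing of whole mouse liver was used from 54 libraries, 1 liver each, in 3 genotypes (WT, KO and RE) at 6 times of day 4 h apart (ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20, in hours after lights on), with 3 livers in each of the 18 groups. Per the submitters' processing notes, reads were aligned to mm10 with TopHat; the TopHat version, the tool that made the expression values and its gene annotation are not given in the sources used here. The deposited table holds FPKM (fragments scaled by transcript length and by mapped fragments) for 24346 gene symbols, so the values had already been scaled by the authors. It holds no read counts, so the depth of each library is unknown and no counting error can be given; precision rests on the spread between livers. Livers are named by genotype, time and the number of their column (0, 1 or 2). Those numbers and the replicate numbers in the sample titles (1 to 3) are different series, and each column was assigned to its group only.

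Values were analysed as log2(FPKM + 1), with a pseudocount of 1. Changes in genes of low FPKM are understated on that scale. A gene was tested if its mean FPKM was at least 1 in any of the 18 groups, which kept 10932 genes and left out 13414, of which 5619 were 0 in all libraries. The 18 group means were fitted in 1 model with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend; 36 residual degrees of freedom). A 24 h rhythm in a genotype was tested with limma's moderated F test of the cosine and sine contrasts over its 6 group means; those contrasts also gave the amplitude (from mean to peak, log2) and the peak time. Rhythm differences between genotypes were tested on the difference of those contrasts, and their size is the length of the difference vector (log2). Level differences are differences between the means over the 6 times, tested two-sided with limma. A 12 h component was tested in the same way, with 3 points per cycle. p values were adjusted by Benjamini and Hochberg over the genes tested, and a call is an adjusted p under 0.05. Peak shifts and amplitude ratios are medians over genes, with an SE from leaving out each library.

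The spread was pooled over genotypes. The median SD within a group was 0.13 in WT, 0.17 in KO and 0.20 in RE, so every comparison was also fitted on the libraries of the genotypes compared alone.

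The tests, the rule for naming genes, 38 gene lists and most alternatives were fixed before the data were examined. The lists cover the core clock, clock output, heat shock, cold-inducible proteins, SRF and immediate early genes, glucocorticoid receptor targets, gluconeogenesis and fasting, PPAR alpha and fat oxidation, lipogenesis, cholesterol synthesis, bile acids, amino acids and urea, xenobiotic metabolism, glycogen and glucose, ribosomal proteins, ribosome biogenesis, unfolded protein, integrated stress, respiratory chain, growth hormone, male-biased genes, female-biased genes, acute phase and cell cycle; markers of pericentral, periportal and all hepatocytes, Kupffer cells, endothelium, stellate cells and fibroblasts, bile duct cells, lymphocytes, neutrophils, red cells, pancreas, muscle and fat; and sex chromosome genes. Some genes are in more than 1 list. Of the listed genes, 6 are absent from the table (Tf, Trbc2, Ighm, Ly6g, Hbb-bt and Ahsp). For each list with at least 3 tested members, the mean of log2(FPKM + 1) per library was fitted with the same contrasts and without a trend, and p was adjusted over 33 lists. The number of members called was counted over all genes and adjusted over the list alone. List members among the calls were compared with all tested genes by a two-sided Fisher's exact test, adjusted over lists; genes are not independent, so it describes only.

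Genes were named by a fixed rule. Gene models without a symbol of their own were counted and not named. Some genes that the rule selects are not reported here. Named were every core clock gene in each comparison; the 10 genes of largest amplitude per genotype and of largest rhythm difference per pair; the 8 largest rises and 8 largest falls in level; up to 4 members per list with the smallest adjusted p, and rate-limiting enzymes; the 10 smallest adjusted p in the sets of rhythms present or lost in RE; and the 5 smallest for 12 h components. The amplitude, difference and level parts required a mean FPKM of at least 5. Genes of the gene families Mup, Serpina1, Ces1, Ugt1a and Cyp2c share sequence, so the division of reads among their members is uncertain. For 22 genes (Alb, Mup1, Mup7, Mup14, Serpina1a, Serpina1b, Serpina1c and 15 small RNA genes), some libraries are listed at 0 and all others lie above 5 FPKM; no fold is given for these. Symbols were placed on mm10 by RefSeq (23143 matched).

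Chance was examined with 100 regroupings of the samples per result, the real one included, with 10000 random lists and with 10000 permutations (seed 1). Alternatives set in advance were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-ratio scaling, robust eBayes, time as a factor, an adjusted p of 0.01, a minimum amplitude of 0.25, a minimum level change of 0.5, a harmonic model per genotype, only the genotypes compared, list members scaled to unit SD, and leaving out each of the 54 libraries. Chosen after seeing the data were leaving out 2 libraries that stand apart, leaving out the 22 genes above, the column number as a block, exchanging 1 pair of genotypes at a time for sets that join 2 comparisons, and, for named genes and lists, only the genotypes compared.

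The steps were tested on simulated data with the spread of these libraries and 200 changed genes of 10932. Noise was drawn independently for each gene, so genes that vary together were not simulated. At an amplitude of 0.25, 0.5 and 1 on the log2 scale, 56.7%, 91.0% and 100% of rhythms were recovered in WT, and 61.2%, 94.0% and 100% in RE. Rhythm differences between RE and KO of those sizes were recovered in 29.9%, 82.1% and 98.5%. Of 10732 unchanged genes, 9 were called rhythmic in WT, 41 in KO and 97 in RE, and 31 were called different in rhythm between RE and KO. These false calls made up 5.17% of the simulated calls in WT, 19.8% in KO, 36.3% in RE and 18.1% for RE against KO. In the simulation, an adjusted p under 0.05 with the pooled spread therefore did not hold false calls to that share in KO, in RE or between them. For level differences between KO and WT, 61.2%, 94.0% and 100% were recovered and 11 unchanged genes were called. Of the list means, the 1 moved list and 1 of the unmoved lists were called. With independent genes, this did not test list means whose members vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.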

Results

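Liver RNA was measured in mice that express Bmal1 (gene symbol Arntl) in all tissues (WT), in mice whose Bmal1 gene carries a floxed STOP sequence (KO), and in mice in which Syt10-Cre removes that sequence in the suprachiasmatic nucleus, the brain's central clock (RE). By design RE livers are to lack Bmal1 and sit in an animal whose central clock has it, so the comparisons ask which daily rhythms and which levels of liver transcripts go with each clock. Each of the 18 groups (3 genotypes at 6 times) had 3 livers. Total FPKM per library ran from 572995 to 751399, and 14654 to 15810 genes lay above 0. All libraries had Y-linked Ddx3y between 6.65 and 22.3 FPKM and Xist at or below 0.0827 FPKM.

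Arntl (chromosome 7, 113178471 to 113314126, mm10) was read in every library. It ranged from 0.202 to 10.3 FPKM over the 18 WT livers, from 9.76 to 14.2 over the 18 KO livers and from 7.60 to 15.5 over the 18 RE livers. The mean was 4.78 ± 4.02 FPKM in WT, 12.0 ± 1.26 in KO and 11.4 ± 2.12 in RE (SD, n = 18 each). The level was higher than in WT by 1.63 (log2, SE 0.07, adjusted p 5.83e-22) in KO and by 1.55 (adjusted p 3.93e-21) in RE, at each of the 6 times. These values cover the whole gene, so they check nothing of the STOP allele or of the protein. In WT, Arntl cycled with an amplitude of 1.72 (log2, SE 0.07) and a peak at ZT21.4. In KO the amplitude was 0.11 and was not called (adjusted p 0.703). In RE it was 0.31 with a peak at ZT0.635 (adjusted p 0.00238).

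**Figure D1:**
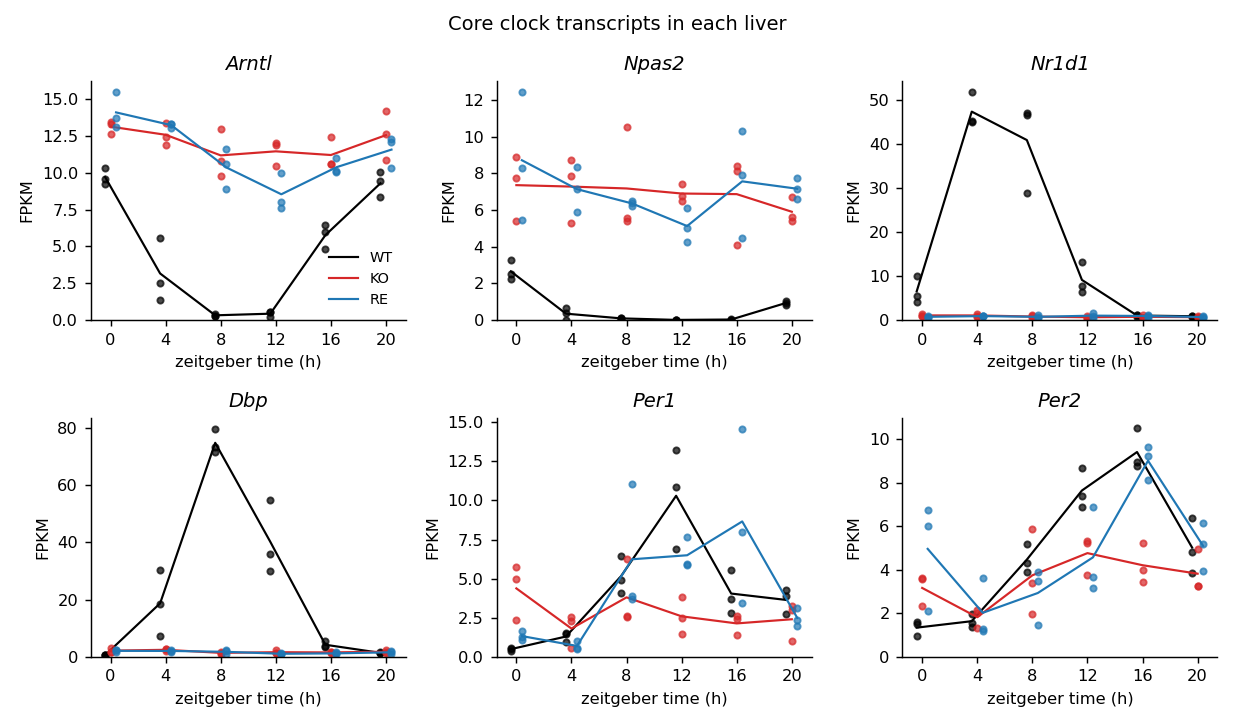
FPKM of Arntl, Npas2, Nr1d1, Dbp, Per1 and Per2 against time of day (ZT, h) in WT, KO and RE livers; points are single livers (3 per group) and lines join group means. Nr1d1 and Dbp cycle in WT with amplitudes of 2.61 and 2.87 (log2) and were not called in KO or RE, while Per1 cycles with 1.23 in WT and 1.18 in RE.

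The WT series shows which liver transcripts cycle when every clock is present. In WT, 3801 of 10932 tested genes had a 24 h rhythm (34.8%; 4897 at an unadjusted p under 0.05, against 547 by chance), with a median amplitude of 0.25 (log2); 197 of them are gene models that are not named. All 19 core clock genes were called, over all genes and adjusted over the list alone, which was more than the 6.61 expected (adjusted p 6.15e-08). Activators and repressors peaked at different times: Arntl at ZT21.4, Clock at ZT21.7, Npas2 at ZT23.4, Nr1d1 at ZT6.19, Nr1d2 at ZT9.26, Dbp at ZT9.15, Per1 at ZT12.6, Per2 at ZT14.2 and Cry1 at ZT18.8. Among genes with a mean of at least 5 FPKM in WT, the largest amplitudes belonged to Rgs16 (2.97, SE 0.33, peak ZT8.33), Dbp (2.87, SE 0.11) and Nr1d1 (2.61, SE 0.09). Next came Mir8094 and Mup12, Usp2 (1.90, peak ZT12.7), Elovl3 (1.83, ZT22.8), the metallothionein Mt1 (1.77, ZT10.2), Gpcpd1 (1.71, ZT9.91) and Tubb2a (1.70, ZT22.4). The core clock genes Ciart (1.84, ZT11.2) and Arntl, named at any mean FPKM, had amplitudes in that range. Mir8094 was listed at 0 in 13 WT libraries, and the Mup genes share sequence. All 16 clock output genes were called (16 adjusted over the list alone), among them Gys2, which encodes glycogen synthase (0.96, ZT12.2), Wee1 (1.12, ZT12.3), Insig2 (1.26, ZT22.9) and Nampt (0.84, ZT14.2).

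Heat shock genes followed in WT, with 17 of 18 called (17 adjusted over the list alone) and a list mean that cycled by 0.50 (SE 0.06) around a peak at ZT18.3 (adjusted p 2.97e-09). Hsph1 (1.18, ZT17.8), Hsp90aa1 (0.95, ZT19.2), Hspa4l (0.72, ZT19.7) and Dnaja1 (0.59, ZT16.2) peaked between ZT16.2 and ZT19.7. The glucocorticoid receptor targets peaked as a list at ZT12.1 (0.55, SE 0.15, adjusted p 0.009999, 8 of 12 called, 8 adjusted over the list alone), with Fkbp5 at ZT13.3 and Tsc22d3 at ZT16.3. The ATF4 targets of the integrated stress list peaked at ZT1.87 (0.23, adjusted p 0.00208, 7 of 10, 7 adjusted over the list alone), led by Atf5 (0.97, ZT0.926) and Trib3 (0.91, ZT6.16). Xenobiotic metabolism peaked at ZT14.8 (0.23, adjusted p 0.00319, 8 of 22, 8 adjusted over the list alone) through Por (1.30, ZT12.2), Alas1 (1.52, ZT12.9) and Cyp2a5 (1.43, ZT13.5). Its member count was near the 7.65 expected from all tested genes. Glycogen and glucose genes peaked at ZT14.3 (0.24, adjusted p 0.00158, 9 of 13, 9 adjusted over the list alone). Weaker list means were called for amino acids and urea (0.20, adjusted p 0.0400, 14 of 25, 16 adjusted over the list alone) and ribosome biogenesis (0.21, adjusted p 0.0400, 10 of 18, 11 adjusted over the list alone). They were also called for SRF and immediate early genes (0.18, adjusted p 0.0473, 6 of 13, 6 adjusted over the list alone, with Junb at ZT5.50) and for bile duct markers (0.33, adjusted p 0.0352, 3 of 5, 3 adjusted over the list alone, with Krt19 at ZT0.118). For the SRF and immediate early genes, 4.52 called members were expected from all tested genes (Fisher p 0.394). Among WT livers the bile duct mean was highest in ZT0 liver 0 (2.86), the library with gut transcripts. Each of these last 4 calls ended without some single WT liver, with adjusted p up to 0.128 for amino acids and urea (12 livers), 0.148 for ribosome biogenesis (11 livers), 0.207 for SRF and immediate early genes (13 livers) and 0.143 for bile duct markers (ZT0 liver 0, ZT4 liver 0, ZT12 liver 0 and ZT16 liver 1).

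List means of lipid metabolism were not called in WT. Cholesterol synthesis had 0.15 (adjusted p 0.680, 6 of 25 genes, 2 adjusted over the list alone) and lipogenesis 0.24 (adjusted p 0.128, 10 of 21, 11 adjusted over the list alone). PPAR alpha and fat oxidation had 0.02 (adjusted p 0.970, 8 of 26, 8 adjusted over the list alone). Single members cycled, among them Thrsp (1.52, ZT14.8), Pdk4 (1.19, ZT21.8), Hmgcs1 (0.81, ZT1.78) and Cyp7a1, which encodes the rate-limiting enzyme of bile acid synthesis (1.12, ZT12.3, adjusted p 0.000609). Both cold-inducible genes cycled in WT, Cirbp (0.58, ZT6.42) and Rbm3 (0.49, ZT11.9), as they did in RE (0.50, ZT6.83, and 0.61, ZT14.0). Of the ribosomal protein genes, 0 of 36 were called in WT by limma (0 adjusted over the list alone), fewer than expected (adjusted p 2.97e-06). Other list means not called in WT were gluconeogenesis and fasting (7 of 15), bile acids (8 of 17, 10 adjusted over the list alone), unfolded protein (13 of 19; list mean 0.29, adjusted p 0.0610), respiratory chain (1 of 21), acute phase (6 of 16), cell cycle (3 of 14) and pericentral markers (5 of 12).

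The KO series tests what is left of these rhythms where the STOP allele is in place in both tissues. Only 4 genes had a 24 h rhythm in KO at an adjusted p under 0.05 in limma, among them Fam47e (0.55, ZT19.1, adjusted p 0.0343), Fgfrl1 (0.37, ZT5.93, adjusted p 0.00623) and Mgrn1 (0.19, ZT4.44, adjusted p 0.0151). At an unadjusted p under 0.05 there were 1301 genes against 547 by chance, and the median amplitude of all tested genes was 0.08, against 0.14 in WT. The KO count rested on single livers: it fell to 0 without KO ZT16 liver 1 or liver 2, to 1 without KO ZT4 liver 2, and to 2 without KO ZT4 liver 0, KO ZT8 liver 2 or KO ZT20 liver 2. It rose to 161 without KO ZT8 liver 1 and to between 7 and 16 without KO ZT20 liver 0, RE ZT0 liver 0, RE ZT8 liver 0, 1 or 2, RE ZT16 liver 0 or RE ZT20 liver 2. With the KO libraries alone, 1 gene model and none of the 4 genes was called (1098 at an unadjusted p under 0.05). No core clock gene was called in KO; Per2 had the largest KO amplitude among them (0.40, adjusted p 0.238). No list mean was called in KO either. Adjusted over the list alone, 9 heat shock, 9 unfolded protein, 7 cell cycle, 6 acute phase, 2 bile acid, 2 female-biased and 1 male-biased gene were rhythmic in KO, against 0 of each over all genes.

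Rhythms differed between WT and KO in 990 genes (2563 at an unadjusted p under 0.05), of which 967 cycled in WT. All 19 core clock genes differed (19 adjusted over the list alone), as did 13 of 16 clock output genes (16 adjusted over the list alone). Among core clock genes and genes with a mean of at least 5 FPKM in either genotype, the largest differences were in Dbp (2.98, adjusted p 2.82e-17), Rgs16 (2.63, adjusted p 0.000539), Nr1d1 (2.52, adjusted p 5.90e-17), Mt1 (2.45, adjusted p 0.0461), Ciart (1.89), Upp2 (1.78), Usp2 (1.78), Tubb2a (1.77), Arntl (1.63), Gpcpd1 (1.62) and Chka (1.60). Per1, whose product represses the clock and whose gene also responds to hormones, had an amplitude of 1.23 in WT and 0.11 in KO (difference 1.32, adjusted p 0.000101). Heat shock genes differed as a list (0.32, adjusted p 0.0103, 7 of 18, 12 adjusted over the list alone), through Hspb1 (0.86), Hspa4l (0.50), Hsph1 (0.73) and Hsp90aa1 (0.60). Glucocorticoid receptor targets differed by 0.79 (adjusted p 0.0160, 2 of 12, 3 adjusted over the list alone). Integrated stress genes differed by 0.28 (adjusted p 0.0160, 3 of 10, 5 adjusted over the list alone, among them Atf5 and Trib3), and xenobiotic metabolism by 0.28 (adjusted p 0.0170, 5 of 22, 6 adjusted over the list alone, among them Por and Cyp2a5). Cyp7a1 differed by 1.37 (adjusted p 0.0106). Without KO ZT8 liver 1 the call of Rora ended (adjusted p 0.0502), and without KO ZT16 liver 2 that of the integrated stress list did (adjusted p 0.0518).

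The RE series tests which liver rhythms are present when, by design, the central clock alone carries Bmal1. In RE, 5116 genes cycled (46.8%; 5957 at an unadjusted p under 0.05) with a median amplitude of 0.24, and 2233 of them also cycled in WT, against 1779 if the calls were independent. The pooled spread is smaller than that of the RE livers; with the RE libraries alone 3107 genes were called in RE, and with the WT libraries alone 5289 in WT. Among genes with a mean of at least 5 FPKM, the largest RE amplitudes were those of Angptl4, an inhibitor of lipoprotein lipase induced by fasting (2.03, SE 0.30, peak ZT10.2, adjusted p 9.90e-06), the fat oxidation gene Cyp4a10 (1.59, ZT10.2), Mfsd2a (1.56, ZT12.9), the haem synthesis enzyme Alas1 (1.37, ZT13.7) and the iron hormone Hamp (1.34, ZT10.8). Serpina1a, Serpina1c and Mup17 were also among them, with libraries listed at 0 or shared sequence, as were Mt1 (1.60) and Mt2 (1.53). With the RE libraries alone the calls of Cyp4a10 (adjusted p 0.0540), Mt1 (0.0713) and Mt2 (0.0976) ended. Cholesterol synthesis cycled in all 25 genes (25 adjusted over the list alone), with a list mean of 0.66 (SE 0.12) that peaked at ZT23.7 (adjusted p 0.000286). PPAR alpha and fat oxidation followed with 23 of 26 genes (24 adjusted over the list alone; 0.58, SE 0.10, ZT9.48, adjusted p 0.000123). Lipogenesis had 15 of 21 (15 adjusted over the list alone; 0.45, SE 0.10, ZT23.2, adjusted p 0.00107) and glucocorticoid receptor targets 10 of 12 (10 adjusted over the list alone; 0.78, SE 0.15, ZT11.5, adjusted p 0.000286). Heat shock genes had 17 of 18 (17 adjusted over the list alone; 0.27, SE 0.06, ZT18.2, adjusted p 0.000747).

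**Figure D2:**
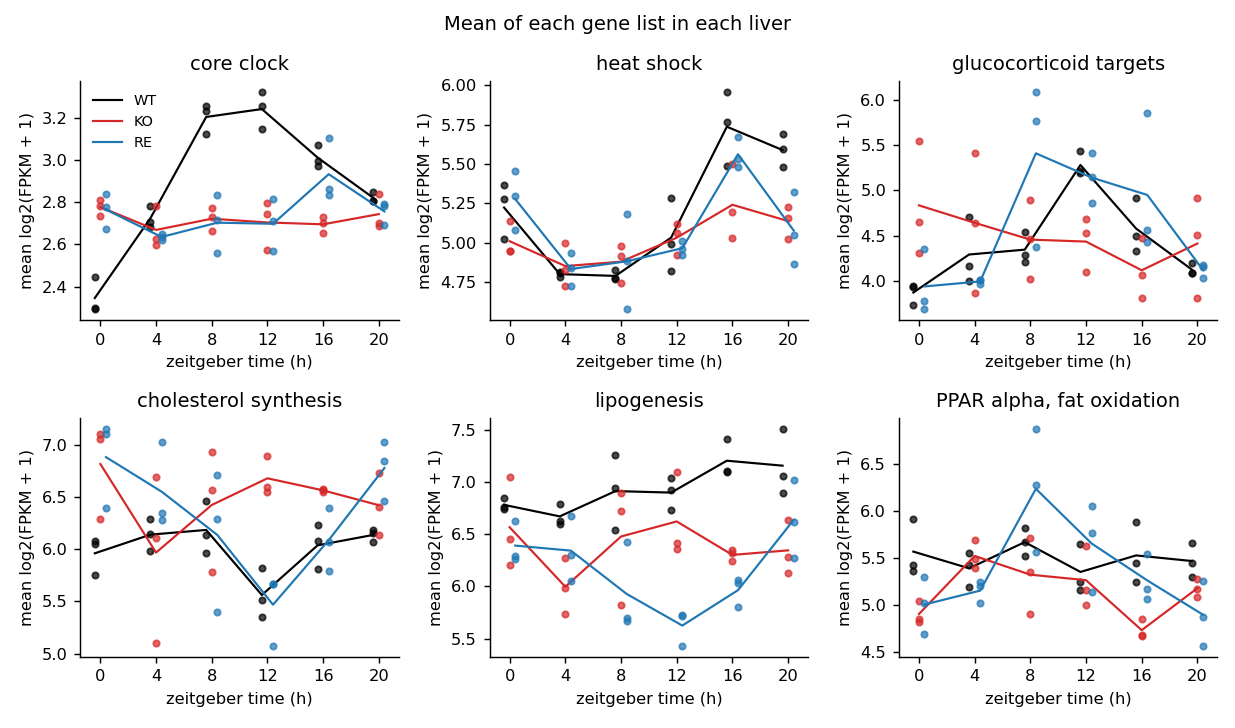
Mean log2(FPKM + 1) of 6 gene lists against time of day (ZT, h) in WT, KO and RE; points are single livers (3 per group) and lines join group means. The cholesterol synthesis mean cycles by 0.66 in RE and by 0.15 in WT, though the direct difference was not called (0.52, adjusted p 0.0686), and the core clock mean by 0.41 in WT and 0.10 in RE.

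Other list means called in RE were glycogen and glucose (0.23, ZT14.2, adjusted p 0.00107, 7 of 13, 7 adjusted over the list alone, with Stbd1 at ZT12.8 and Pfkfb3 at ZT13.9) and clock output (0.23, ZT13.9, adjusted p 0.000752, 7 of 16, 7 adjusted over the list alone). So were ribosome biogenesis (0.28, ZT14.1, adjusted p 0.00280, 13 of 18, 15 adjusted over the list alone, with Npm1 and Rrs1) and gluconeogenesis and fasting (0.35, ZT12.7, adjusted p 0.0146, 8 of 15, 8 adjusted over the list alone). Some member counts were near those expected from all tested genes. These were glycogen and glucose (7 against 6.08), clock output (7 against 7.49), gluconeogenesis and fasting (8 against 7.02) and the core clock (8 against 8.89). Periportal markers (0.25, ZT23.3, adjusted p 0.00417, 6 of 10, 6 adjusted over the list alone, with Arg1 at ZT19.1) and sex chromosome genes (0.24, ZT16.2, adjusted p 0.00280, 3 of 4, 3 adjusted over the list alone, with Ddx3y) were called as well, and so were hepatocyte markers, whose mean rests on Alb and Serpina1c in libraries listed at 0. The core clock mean was called with 0.10 (adjusted p 0.0317, 8 of 19, 7 adjusted over the list alone). That call ended (adjusted p up to 0.170) without any 1 of RE ZT4 liver 0 or 1, RE ZT8 liver 0, RE ZT16 liver 2 or RE ZT20 liver 1 or 2, and with the RE libraries alone (0.249). Without RE ZT0 liver 2 the periportal call ended (0.0512), and without RE ZT0 liver 0 or RE ZT12 liver 1 that of gluconeogenesis and fasting did (up to 0.0872). With the RE libraries alone, gluconeogenesis and ribosome biogenesis were not called either (0.0596 each). The 8 core clock genes called in RE included Per1 (1.18, SE 0.15, ZT13.4), Per2 (0.74, ZT17.1), Clock (0.36, ZT17.1), Arntl (0.31), Rora (0.29), Per3 (0.25, ZT21.8) and Ciart (0.19). Nr1d1 (0.06), Dbp (0.30, adjusted p 0.0610), Tef (0.07), Cry1 (0.23), Npas2 (0.23), Nr1d2 (0.24), Nfil3 (0.24), Cry2 (0.14), Bhlhe40 (0.12), Hlf (0.08) and Bhlhe41 (0.01) were not called. Xenobiotic (0.02; 6 of 22), bile acid (7 of 17), amino acid and urea (0.19, adjusted p 0.0526, 13 of 25, 15 adjusted over the list alone) and unfolded protein (7 of 19) means were not called in RE. Neither were integrated stress (3 of 10), respiratory chain (7 of 21), SRF and immediate early (5 of 13), acute phase (3 of 16), cell cycle (7 of 14, 8 adjusted over the list alone), ribosomal protein (2 of 36) or pericentral (4 of 12) means.

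Of the 2233 genes that cycled in both WT and RE, 1492 (66.8%) peaked within 3 h of each other and 237 over 6 h apart. Their median peak shift was 0.65 h later in RE (SE 0.909) and their median log2 amplitude ratio was 0.03 (SE 0.27), both smaller than their error. Rhythms differed between WT and RE in 1538 genes, of which 1009 cycled in WT, 555 in both, and 490 in RE and not WT. Of the 19 core clock genes, 17 differed (17 adjusted over the list alone); Per1 (0.23, adjusted p 0.706) and Rora (0.19, adjusted p 0.347) did not pass. Among core clock genes and genes with a mean of at least 5 FPKM in either genotype, the largest differences apart from Serpina1c were in Dbp (2.97), Nr1d1 (2.60), Rgs16 (2.45, adjusted p 0.00111), Elovl3 (2.05), Cdkn1a (2.03, from 1.33 at ZT21.0 in WT to 1.07 at ZT13.3 in RE), Upp2 (1.93), Cyp2a5 (1.89), Ciart (1.84), Thrsp (1.78, from ZT14.8 to ZT20.3) and Serpina7 (1.60, adjusted p 0.0195). Clock output genes differed in 14 of 16 (15 adjusted over the list alone). Lipogenesis differed as a list (0.54, adjusted p 0.0194, 12 of 21, 14 adjusted over the list alone), with Srebf1 at ZT12.3 in WT and ZT22.4 in RE, and Fads2 at ZT12.0 and ZT3.15. PPAR alpha and fat oxidation differed by 0.58 (adjusted p 0.0114, 11 of 26, 17 adjusted over the list alone), with Pdk4 at ZT21.8 in WT and ZT3.20 in RE. The cholesterol synthesis mean did not pass (0.52, adjusted p 0.0686, 8 of 25, 13 adjusted over the list alone). Amino acid and urea genes were called in 12 of 25 (13 adjusted over the list alone; list mean adjusted p 0.0686), among them Gpt and Prodh. Bile acid genes were called in 7 of 17 (11 adjusted over the list alone), among them Cyp8b1, whose amplitude was 0.07 in WT and 1.03 in RE. Glucocorticoid receptor targets differed in 0 of 12 genes by limma (0 adjusted over the list alone; list mean 0.25, adjusted p 0.731), and the glycogen and glucose mean by 0.01 (adjusted p 0.9896, 3 of 13, 4 adjusted over the list alone).

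**Figure D3:**
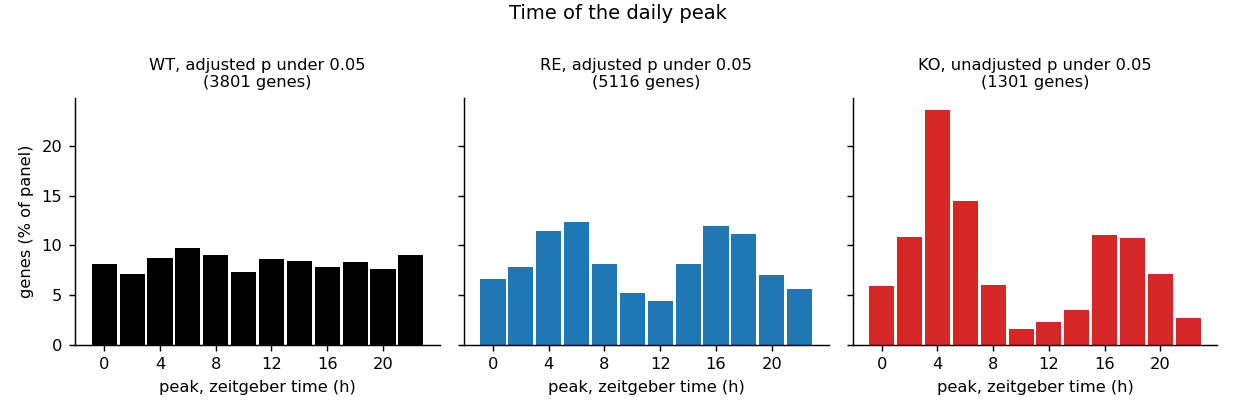
Peak times (ZT, in bins of 2 h) of rhythmic genes as a percentage of each genotype's genes, for the 3801 genes called in WT, the 5116 called in RE, and the 1301 with an unadjusted p under 0.05 in KO. From ZT3 to ZT7 lie 18.5% of WT, 23.8% of RE and 38.1% of KO peaks.

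The comparison of RE with KO asks what the central clock adds to a liver with the STOP allele, between animals that also differ by the Syt10-Cre allele. Rhythms differed in 336 genes (2579 at an unadjusted p under 0.05), all 336 of them called rhythmic in RE. Among genes with a mean of at least 5 FPKM, the largest differences were in Angptl4 (2.21, adjusted p 0.0120), the lipid transporter Mfsd2a (1.54, adjusted p 0.0224) and Pck1, the rate-limiting gluconeogenic enzyme, which cycled by 1.24 (SE 0.20, peak ZT12.5) in RE and by 0.16 in KO (difference 1.40, adjusted p 0.0166). Enzymes of fat and sterol synthesis peaked near the end of the night in RE, such as Acly (1.16, SE 0.16, ZT23.5; difference 1.33, adjusted p 0.00471) and Fasn (1.06, SE 0.19, ZT22.4; 1.32, adjusted p 0.0177). So did Acacb (1.13, ZT0.791; 1.19), Lss (1.02, SE 0.17, ZT23.5; 1.14, adjusted p 0.0218) and Hmgcs1 (0.95, ZT0.189; 1.13, adjusted p 0.0360). Ccrn4l (1.24) and Cml5 (1.23) complete the 10 largest. As a list, glucocorticoid receptor targets differed by 0.99 (adjusted p 0.00377, 2 of 12 genes, 7 adjusted over the list alone). Cholesterol synthesis differed by 0.72 (adjusted p 0.0154, 12 of 25, 23 adjusted over the list alone, among them Dhcr7 and Insig1), and lipogenesis by 0.53 (adjusted p 0.0235, 4 of 21, 10 adjusted over the list alone, among them Gpam). PPAR alpha and fat oxidation had 5 of 26 genes called (10 adjusted over the list alone; list mean 0.45, adjusted p 0.0720), among them Cpt1a (0.63) and Slc25a20 (0.53). The DNA replication genes Mcm2, Mcm3, Mcm4, Mcm5 and Mcm6 were the 5 of 14 cell cycle genes called (6 adjusted over the list alone; list mean 0.42, adjusted p 0.0800). Gluconeogenesis and fasting had 2 of 15 (4 adjusted over the list alone), Pck1 and G6pc (0.94, adjusted p 0.0479). Of the core clock, Per1 alone was called (1.28, adjusted p 0.00471, 1 adjusted over the list alone). Per2 differed by 0.46 (adjusted p 0.175), and heat shock genes in 0 of 18 by limma (0 adjusted over the list alone; list mean 0.09, adjusted p 0.657).

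**Figure D4:**
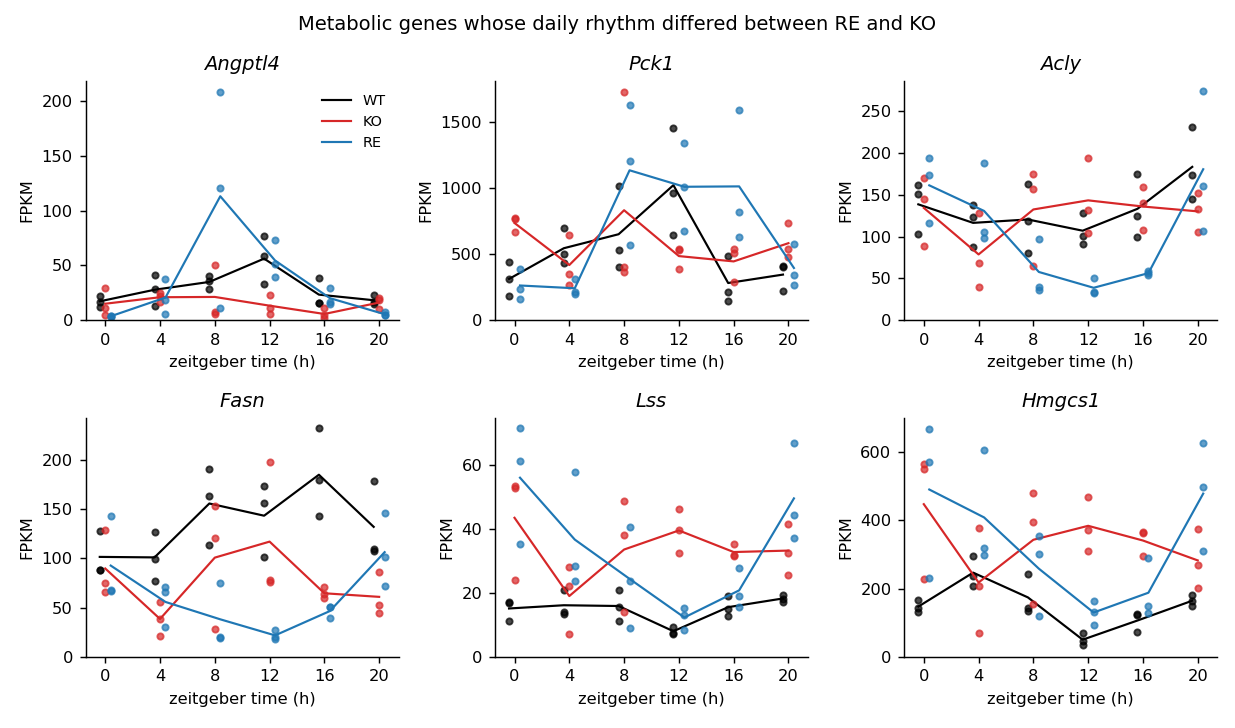
FPKM of Angptl4, Pck1, Acly, Fasn, Lss and Hmgcs1 against time of day (ZT, h) in WT, KO and RE; points are single livers (3 per group) and lines join group means. Angptl4 and Pck1 peak at ZT10.2 and ZT12.5 in RE, and Acly, Fasn, Lss and Hmgcs1 between ZT22.4 and ZT0.189.

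The count of 336 depended on the spread, the model, the threshold and the filter used, and on single livers. It was 15 with time as a factor, 15 at an adjusted p under 0.01 and 191 without a filter. With only the RE and KO libraries, 2 genes were called, Ablim1 and Homer2 (1902 at an unadjusted p under 0.05); there the adjusted p was 0.0658 for Per1, Acly and Rcl1, 0.0761 for Pck1 and Ptpn21, and 0.0939 for Angptl4. The glucocorticoid list was called there too (0.0412), and the cholesterol and lipogenesis lists were not (0.0751 each). The count fell to between 145 and 223 without RE ZT12 liver 2 (145), KO ZT4 liver 1, RE ZT4 liver 0 or 1, KO ZT0 liver 1, KO ZT12 liver 2, KO ZT16 liver 0 or 1, or RE ZT20 liver 0. It rose to between 508 and 687 without KO ZT8 liver 2 (687), RE ZT8 liver 0 or 2, RE ZT20 liver 2, KO ZT4 liver 2, KO ZT16 liver 2 or RE ZT16 liver 1. The cholesterol list call ended without KO ZT0 liver 1 (0.0688), and that of lipogenesis without KO ZT0 liver 1, KO ZT12 liver 2 or RE ZT0 liver 0 (up to 0.0930).

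Putting these tests together, 69 genes cycled in WT and in RE and differed from KO in both. Among the 10 with the smallest adjusted p for RE against KO were Ablim1 (0.76), Per1 (1.28), Rcl1 (0.51), Ptpn21 (0.27), Homer2 (0.32), the lectin Mbl1 (0.31), Pter (0.56), Bfar (0.35) and Ric8 (0.27). Of the 69, 24 also differed between WT and RE, such as Mbl1, which peaked at ZT1.56 in WT and ZT10.7 in RE, and Homer2, at ZT14.8 and ZT19.8. With only the RE and KO libraries, the step from KO to RE was passed by 2 of the genes, Ablim1 and Homer2. The number fell to between 30 and 44 without KO ZT4 liver 1 (30), RE ZT4 liver 0 or 1, RE ZT12 liver 2, KO ZT12 liver 2, KO ZT16 liver 0 or 1, KO ZT0 liver 1 or 2, or RE ZT20 liver 0, and rose to between 108 and 142 without KO ZT8 liver 2 (142), KO ZT4 liver 2, KO ZT16 liver 2, RE ZT8 liver 0 or RE ZT16 liver 1. Another 264 genes cycled in WT, differed from WT in both KO and RE, and were called in neither. Among the 10 with the smallest adjusted p for WT against RE were Dbp, Nr1d1, Tef (1.33, adjusted p 1.59e-13), Nrg4 (1.00), Pcsk4 (1.01), Dtx4 (0.80), Cry1 (1.14), Lgalsl (0.98) and Hacl1 (0.88). The 264 included 11 of 19 core clock genes (adjusted p 2.79e-12) and 6 of 16 clock output genes (adjusted p 2.02e-05). Of the 967 genes that cycled in WT and differed in rhythm between WT and KO, 536 were called rhythmic in RE, with or without a difference from KO. For comparison, 46.8% of all tested genes were called rhythmic in RE.

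Levels over the day were compared to see what goes with the STOP allele apart from rhythm. Between KO and WT, 4620 genes differed (2415 higher and 2205 lower in KO), with a median size of 0.25 (log2); 118 rose and 118 fell by at least 1. The labels give no library batch, so a batch that goes with WT was not tested. Lipoprotein lipase, Lpl, rose from 5.51 ± 3.17 FPKM in WT to 113 ± 32.5 in KO (SD, n = 18; log2 4.21, SE 0.11, adjusted p 3.75e-29). Oestrogen sulphotransferase Sult1e1 rose from 0.295 to 42.7 FPKM (4.40, SE 0.32), and the cytochrome P450 genes Cyp2b10 (4.45 to 73.7 FPKM, log2 3.82, SE 0.21) and Cyp2c55 (2.87 to 57.7 FPKM, log2 3.89), Spink1 (3.43 to 26.3 FPKM, log2 3.15), Slc34a2 (3.11) and Loxl4 (3.02) also rose. Nat8 fell from 57.7 ± 20.7 to 0.663 ± 0.387 FPKM (-5.08, SE 0.10, adjusted p 5.71e-34). Tff3 (-3.44), Serpina1e (-3.39), Serpina4-ps1 (-3.38), Cml5 (-3.25), Mme (-2.77), Mup17 (-2.76) and Ces1d (579 to 94.5 FPKM, log2 -2.68) fell as well. Each of these rises and falls held at all 6 times except that of Mup17, which held at 5. Alb, Mup7 and Mup14 were listed at 0 in all 18 WT libraries. Alb lay between 9890 and 19950 FPKM in all but 3 of the other libraries, so its 0 values are read as a property of the table and no change is given; the hepatocyte list (6 higher and 3 lower of 11) contains Alb, and its mean is not read.

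Of the core clock, 7 genes were higher and 8 lower in KO (15 adjusted over the list alone). Npas2 (0.680 to 6.92 FPKM, log2 2.39), Arntl (1.63) and Cry1 (1.43) rose, as did Clock (0.35), Cry2 (0.31) and Nfil3 (0.43). Nr1d1 (17.7 ± 20.1 to 0.833 ± 0.308 FPKM, log2 -2.31), Nr1d2 (-2.16), Dbp (-1.85), Ciart (-1.59), Per3 (-0.99), Tef (-0.54), Bhlhe41 (-0.53) and Hlf (-0.34) fell. Per1 (-0.21, adjusted p 0.260), Per2 (-0.21, adjusted p 0.145), Bhlhe40 (-0.22, adjusted p 0.117) and Rora (-0.01) were not called. Among clock output genes 6 rose, such as Cdkn1a (4.11 to 21.1 FPKM, log2 2.28), and 9 fell (15 adjusted over the list alone), such as Gys2 (-1.39) and Rgs16 (-2.53). The lists' own means fell by 0.17 and by 0.32; the core clock call ended when members were scaled to unit SD.

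Fat synthesis and oxidation genes were lower in KO. The lipogenesis mean fell by 0.55 (SE 0.10, adjusted p 2.04e-05), with 14 of 21 genes lower and 0 higher (15 adjusted over the list alone), among them Fads2 (-0.99), Pnpla3 (-1.31), Fasn (-0.93, SE 0.19) and Scd1 (3122 to 1412 FPKM, log2 -1.32). PPAR alpha and fat oxidation fell by 0.34 (SE 0.10, adjusted p 0.00442), with 19 of 26 genes lower and 3 higher (22 adjusted over the list alone); Acaa1b (-1.44), Ppara (-0.85) and Cpt1a, the rate-limiting step (-0.54), fell, and Pdk4 rose (1.54). Cholesterol synthesis rose by 0.48 (SE 0.12, adjusted p 0.00189), with 17 of 25 genes higher and 2 lower (20 adjusted over the list alone): Hmgcs1 rose from 148 ± 68.8 to 336 ± 134 FPKM (1.21, SE 0.19), Lss by 1.06 and Mvk by 0.94. Amino acid and urea genes rose by 0.26 (SE 0.06, adjusted p 0.00104; 13 higher and 3 lower of 25, 16 adjusted over the list alone), led by Agxt (235 to 556 FPKM, log2 1.25), Cbs (0.92) and Bhmt (0.98). Ribosomal protein genes rose by 0.23 (SE 0.06, adjusted p 0.00104), with 32 of 36 higher and 0 lower (33 adjusted over the list alone), such as Rpl3 (0.34) and Rpl4 (0.27). Cell cycle genes rose by 0.28 (SE 0.10, adjusted p 0.0129; 9 higher and 2 lower of 14, 11 adjusted over the list alone), with Mcm6 up from 1.92 to 5.78 FPKM (1.11) and Ccnd1 down (-0.92). Gluconeogenesis and fasting rose by 0.24 (adjusted p 0.0431; 6 higher and 3 lower of 15, 9 adjusted over the list alone), with Igfbp1 (1.55) and Got1 (0.86); that call ended under 19 changes, with adjusted p up to 0.239.

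Xenobiotic genes went both ways in KO, 7 higher and 10 lower of 22 (17 adjusted over the list alone). Gstm2 (92.7 to 534 FPKM, log2 2.52) and Gstm3 (2.68) rose with Cyp2b10, and Cyp2a5 fell (422 to 87.4 FPKM, log2 -2.04); the list mean of 0.28 (adjusted p 7.00e-05) turned to -0.04 when members were scaled to unit SD. Male-biased genes were lower as a list (-0.51, SE 0.18, adjusted p 0.0197; 2 higher and 8 lower of 15, 10 adjusted over the list alone), with Cyp4a12a at -1.41 and Elovl3 rising (1.29). So were female-biased genes (-0.30, adjusted p 0.00938; 2 higher and 4 lower of 7, 6 adjusted over the list alone), with Cyp17a1 (-1.55) and Acot3 (-1.50) falling. Both calls ended with a pseudocount of 0.1 (adjusted p 0.0537 and 0.235). The growth hormone mean fell by 0.26 (adjusted p 0.0288, 2 of 7 lower, 2 adjusted over the list alone, Igf1 and Igfals). It passed 0.05 without any 1 of WT ZT0 liver 1, WT ZT16 liver 1, KO ZT0 liver 2, KO ZT4 liver 2, KO ZT12 liver 2 or KO ZT16 liver 0 (up to 0.0665). SRF and immediate early genes fell by 0.19 (adjusted p 0.00804, 5 of 13 lower, 5 adjusted over the list alone), with Zyx (-0.48) and Junb (-0.69). Heat shock genes fell by 0.17 (adjusted p 0.0110, 4 of 18 lower, 4 adjusted over the list alone), led by Hspb1 (26.3 to 3.43 FPKM, log2 -2.50), a call that ended under unit SD scaling. Kupffer cell markers fell by 0.34 (adjusted p 0.0243, 5 of 12 lower, 9 adjusted over the list alone), with Vsig4 (-0.46), Marco (-0.69) and Clec4f (-0.41), and not without KO ZT16 liver 0 (adjusted p 0.0554). List means not called for KO against WT were glucocorticoid (4 higher, 4 lower), bile acids (5 and 3, Hsd3b7 0.60), glycogen and glucose (4 and 4, Slc2a2 -1.01), ribosome biogenesis (3 and 0), and unfolded protein (0 and 4, Herpud1 -1.16). Nor were integrated stress (4 and 3, Atf5 0.97, Asns -0.96), respiratory chain (3 and 1), acute phase (8 and 1, Itih3 0.96), pericentral (4 and 2), periportal (3 and 4), endothelial (1 and 4), stellate (1 and 0), bile duct (2 and 0, Spp1 1.23), lymphocyte, red cell or sex chromosome genes. Of the lists too small for a mean, pancreas (Reg1, -0.48) and fat (Cfd, -1.22) had 1 of 2 tested genes lower (Reg1 was 39.3 FPKM in WT ZT0 liver 0, the library with gut transcripts, and 2.30 and 2.29 in the other WT ZT0 livers), the cold-inducible pair 1 higher (Rbm3, 0.27), neutrophil 0 of 2 called by limma, and no muscle gene was tested.

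**Figure D5:**
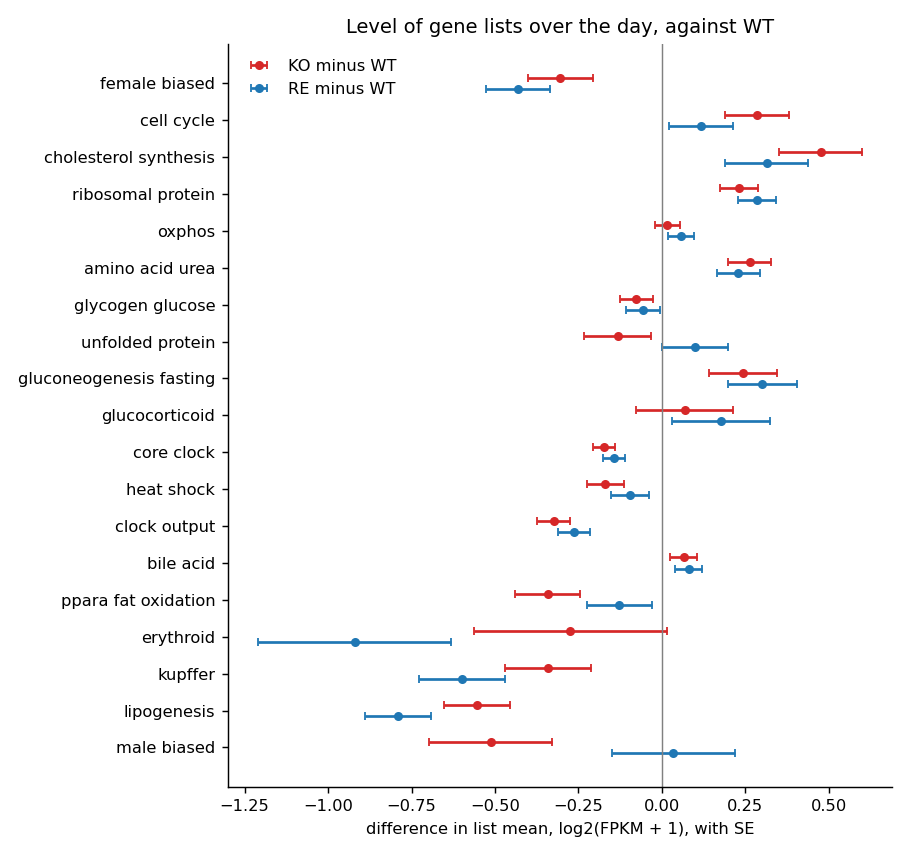
Difference in list mean (log2, KO minus WT and RE minus WT, ± SE) for 19 gene lists; each point is 1 list in 1 comparison of 18 against 18 livers. Lipogenesis lies at -0.55 and -0.79, and cholesterol synthesis at 0.48 and 0.31.

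RE livers differed from WT in level at 5019 genes (2644 higher, 2375 lower; 114 rose and 136 fell by at least 1). The 8 largest rises and falls were again led by Sult1e1 (42.4 FPKM in RE; 4.73), Lpl (97.8; 4.04), Cyp2b10 (75.3; 4.02), Cyp2c55 (3.56), Slc34a2 (3.22), Loxl4 (3.13) and Spink1 (2.92), and by Nat8 (-5.09), Tff3 (-3.22), Ces1d (-3.05), Cml5 (-2.92), Ugt1a9 (-2.87), Mme (-2.82) and Smim22 (-2.61); Alb and Serpina1c complete them. Lipogenesis fell by 0.79 (adjusted p 3.09e-08, 18 of 21 lower, 18 adjusted over the list alone), with Scd1 at -2.20 and Fasn at -1.38. Ribosomal proteins rose by 0.29 (35 of 36 higher, 36 adjusted over the list alone) and amino acid and urea genes by 0.23 (12 higher and 2 lower, 14 adjusted over the list alone). Gluconeogenesis and fasting rose by 0.30 (5 and 2, 7 adjusted over the list alone) and cholesterol synthesis by 0.31 (adjusted p 0.0344, 13 and 4, 17 adjusted over the list alone). The cholesterol call ended under 14 changes (adjusted p up to 0.0800). Kupffer markers fell by 0.60 (adjusted p 0.000223, 12 of 12 lower, 12 adjusted over the list alone), red cell genes by 0.92 (SE 0.29, adjusted p 0.00785, 4 of 6 lower, with Hba-a1 at -1.39) and lymphocyte markers by 0.35 (adjusted p 0.00124, 3 of 3 lower). Female-biased genes fell by 0.43 (4 of 7 lower), SRF and immediate early genes by 0.26 (6 of 13 lower), the core clock by 0.14 and clock output by 0.26. Periportal markers fell by 0.15 (adjusted p 0.0412; 1 higher, 3 lower), a call that ended under 20 changes (up to 0.0844). The bile duct mean rose by 0.26 (adjusted p 0.0321), a call that ended under 11 changes (up to 0.203), and the xenobiotic mean by 0.23. With members scaled to unit SD, the core clock (0.373), gluconeogenesis (0.0784) and xenobiotic (0.537) calls ended. PPAR alpha and fat oxidation (-0.13, adjusted p 0.273), male-biased genes (0.03), cell cycle (0.12), growth hormone (-0.11) and heat shock (-0.10) were not called.

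In 3824 genes the level was called in the same direction in KO and in RE against WT (2018 higher, 1806 lower), and in 0 genes in opposite directions by limma. The comparisons share the WT livers; independent calls would give 584 higher and 479 lower, and separate sets of 9 WT libraries gave 2255 and 2175. The core clock genes Npas2, Cry1, Nr1d1 and Dbp, and Lpl, Nat8, Sult1e1, Cyp2b10 and Mme, were all among those changed in both. Directly between RE and KO, 21 genes differed in level (8 higher in RE, 13 lower; 1451 at an unadjusted p under 0.05). The growth factor Fgf1 rose from 10.9 ± 2.62 FPKM in KO to 16.0 ± 4.59 in RE (SD, n = 18; 0.51, SE 0.09, adjusted p 0.00666), against 24.9 ± 7.67 in WT. Serpina3k (0.49), Apoa1 (0.28), Ttpal (0.28), Rcl1 (0.27), Hadhb (0.22) and Gpr89 (0.14) also rose. Scd1 (1412 to 777 FPKM, log2 -0.87, adjusted p 0.0475), H2-Q1 (-0.69), the corticosteroid-binding globulin gene Serpina6 (-0.54, adjusted p 0.0174), Mov10 (-0.35), Zfp385a (-0.31), Sema4a (-0.27) and Aplp2 (-0.25) fell, and Mup14 was called with WT listed at 0. No list mean was called (lowest adjusted p 0.0940, for male-biased genes, 0.55, and lymphocyte markers, -0.26). With only the RE and KO libraries, 0 genes were called in limma (1112 at an unadjusted p under 0.05). The count was 13 without RE ZT8 liver 2, and between 33 and 172 without RE ZT8 liver 0 (172), RE ZT0 liver 2, RE ZT12 liver 0, RE ZT16 liver 2, RE ZT20 liver 1, KO ZT8 liver 1 or 2, KO ZT12 liver 1 or KO ZT16 liver 2.

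Of the genes changed in KO, 10 moved back in RE: Fgf1, Apoa1, Rcl1 and Hadhb were lower in KO and rose in RE, and 6 were higher in KO and fell in RE, among them H2-Q1, Mov10 and Zfp385a. Mup14 is counted among the 10 but is not read, since it was listed at 0 in 18 WT, 7 KO and 15 RE libraries; without the genes listed at 0, an alternative chosen after seeing the data, the number was 9. Independent calls would give 1.61 and 2.87, and separate sets of 9 KO libraries gave 1 and 0. The number was 6 without RE ZT8 liver 2 and between 18 and 66 without RE ZT8 liver 0 (66), RE ZT0 liver 2, RE ZT16 liver 2, KO ZT8 liver 1 or 2, KO ZT12 liver 1 or KO ZT16 liver 2.

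A 12 h component was called in 27 genes in WT (661 at an unadjusted p under 0.05 against 547 by chance), in 0 in KO (497) and in 0 in RE (987) by limma. The 5 with the smallest adjusted p were Reg3b (1.30), Bhlhe41 (0.33), Tef (0.43), Ciart (0.42) and Cyp46a1 (0.28). The gut transcripts Defa24 and Rbp2 had the same adjusted p in limma as Cyp46a1 (0.00226), which came first by alphabet. Bhlhe41, Tef and Ciart are core clock genes that also had a 24 h rhythm in WT. The fit does not tell a half-day rhythm from a 24 h curve that departs from a cosine. Of the 27, 13 were over 10 times higher in WT ZT0 liver 0 than in the median of the other 51 libraries; Reg3b was 70.6 FPKM there and 6.72 and 6.42 in the other WT ZT0 livers. With a pseudocount of 0.1, Ciart (adjusted p 0.709) and Cyp46a1 (0.410) were not called, and with the WT libraries alone 10 genes were. The count was 16 without WT ZT12 liver 2, 46 without WT ZT0 liver 1 and 50 without WT ZT0 liver 2.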

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

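The tests of the clock genes against random lists, of the WT libraries on the main axis, of a daily rhythm in gut genes, of matching peak times and of the sets that join 2 comparisons were chosen after their results had been seen. Regrouping the samples gave, as real count, highest count of any other split and number of 100 splits at least as large: rhythms in WT 3801, 124, 1; in KO 4, 127, 8; in RE 5116, 2302, 1. Rhythm differences gave 990, 1509 and 4 for WT against KO, 1538, 596 and 1 for WT against RE, and 336, 45 and 1 for RE against KO. Level differences gave 4620, 992 and 1 for KO against WT, 5019, 50 and 1 for RE against WT, and 21, 184 and 5 for RE against KO. For sets that join 2 comparisons, the labels of 1 pair of genotypes were exchanged at a time, and the pair with the larger share is given. The rhythms present in RE gave 69, 78 and 2, those lost 264, 92 and 1, the levels returned 10, 818 and 5, and the shared levels 3824, 48 and 1. The 12 h components gave 27, 576 and 15 in WT, 0, 124 and 100 in KO, and 0, 1569 and 100 in RE. Chance is therefore not excluded for the KO rhythms, the RE against KO levels, the levels returned in RE or the 12 h component in WT. For the 12 h component in KO and in RE the real count was 0. Every split is at least as large as 0, so the regrouping cannot decide anything there. Exchanging WT labels with KO or RE also puts their level differences into the spread within the regrouped groups. That can lower the regrouped counts, so these splits cannot decide on chance for rhythm differences from WT or for the sets of rhythms present or lost. Single splits that called 2302, 1509 or 1569 genes point to a structure of the samples, which was not examined further.

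The levels of 4620 genes differed between KO and WT. Against a technical origin, the core clock changed by a median of 0.54 (log2), beyond the highest of 10000 random lists (0.31; percentile 100), and 94% of 4470 calls kept their sign after GC content and length were fitted. For the other genes a batch that goes with WT was not tested, since no batch is given. The gap of 23.7 units between WT and all other libraries on the main axis restates the level differences and takes in Alb. Depth is unknown, and genes above 0 overlapped between WT (14828 to 15456) and KO (14963 to 15810). Zeros did go with WT for some genes: Alb was listed at 0 in 18 WT libraries, 1 KO library and 2 RE libraries. Mup7 and Mup14 were also at 0 in all 18 WT libraries, and in some KO and RE libraries. On the main axis, the KO and RE libraries nearest WT were those with Alb at 0 (5.77, 6.57 and 9.59). Whether the table differs in WT for further genes was not tested. Without the 22 genes listed at 0, 4614 genes were called. Genes carried along with the targeted Bmal1 locus stay open: 44 of 88 tested genes within 10 Mb were called, against 273 of 695 on the rest of the chromosome (Fisher p 0.0648). Around Syt10, 1 of 295 genes within 20 Mb differed between RE and KO, Zfp385a, against 19 of 10150 elsewhere (p 0.436), which leaves that open too; the loss of Bmal1 that the design intends was not tested against either.

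More genes cycled in RE (5116) than in WT (3801). The library that stands apart, RE ZT16 liver 2, does not explain it, since without it the counts were 4723 and 4045. The spread used is an explanation that fits: with only the genotype's own libraries the order turned, with 3107 in RE and 5289 in WT. An effect of the central clock beyond that in WT stays open as untested.

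Gut transcripts were high in WT ZT0 liver 0, where Reg3b was 70.6 FPKM, Zg16 58.9, Rbp2 55.9 and Defa24 47.6. Of 18 gut markers not used to find the pattern, 16 were highest in that library, as intestinal tissue in the sample would give. A daily rhythm stays open: the 3 WT ZT0 livers differed 19.0-fold in the median of 13 called markers, but 9 of these had been used to find the pattern, and Reg3b was also higher in the other 2 (6.72 and 6.42 FPKM) than in the median of the other 51 libraries (0.0647). Of the 27 genes with a 12 h component in WT, 13 were over 10 times higher in WT ZT0 liver 0, yet the count was 30 without it and 31 without it and RE ZT16 liver 2. Without that liver the bile duct rhythm in WT and its difference from KO were not called.

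Lists whose rhythm differed between genotypes gave these sizes (log2) and adjusted p. RE against KO: glucocorticoid 0.99, 0.00377, cholesterol synthesis 0.72, 0.0154, and lipogenesis 0.53, 0.0235. WT against KO: core clock 0.44, 3.32e-09, clock output 0.44, 1.34e-05, heat shock 0.32, 0.0103, and glucocorticoid 0.79, 0.0160. Also WT against KO: integrated stress 0.28, 0.0160, xenobiotic 0.28, 0.0170, SRF and immediate early 0.27, 0.0452, and bile duct 0.45, 0.0452. WT against RE: core clock 0.41, 1.41e-08, PPAR alpha and fat oxidation 0.58, 0.0114, and lipogenesis 0.54, 0.0194. Also WT against RE: clock output 0.24, 0.0358, and hepatocyte 0.69, 0.0361, the latter resting on Serpina1c and Alb where listed at 0. Leaving out 1 of 22 libraries ended the SRF call (adjusted p up to 0.170), 1 of 19 the bile duct call (0.127), 1 of 16 the hepatocyte call (0.0785), and 1 of WT ZT4 liver 0, WT ZT16 liver 0, KO ZT4 liver 0 or KO ZT16 liver 2 the xenobiotic call (0.0795). The clock output call of WT against RE ended without 1 of WT ZT0 liver 0 or 1, WT ZT4 liver 0, WT ZT8 liver 0, WT ZT12 liver 0, RE ZT4 liver 0 or RE ZT12 liver 2 (0.0723).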

How the results depend on the processing

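Leaving out the 2 libraries that stand apart (WT ZT0 liver 0 and RE ZT16 liver 2) and the column number as a block were chosen after seeing the data; the other alternatives below were planned, and where a count moved the cause was not tested. A block on the replicate number of the titles (1 to 3) was planned and not run, since the columns are numbered 0 to 2 in another series. Libraries with the same column number did not deviate together (mean correlation 0.0031, against -0.0015 for different numbers; 23 of 54 libraries correlated best with their own number). With the column number as a block, rhythms were 3760 in WT, 5 in KO and 5097 in RE, the RE against KO differences 328 in rhythm and 25 in level, and no count moved by over 1.5 times. Without a filter, the RE against KO rhythm difference was 191 (336), the rhythms present in RE 34 (69), and the 12 h component 1 in KO and 1 in RE (0 each); with a filter at 5 FPKM the 12 h component in WT was 17 (27). With time as a factor, rhythm differences were 633 for WT against KO, 830 for WT against RE and 15 for RE against KO. At an adjusted p under 0.01, rhythms were 2299 in WT, 1 in KO and 3348 in RE, and rhythm differences 469, 691 and 15. There the RE against KO level difference was 6, the rhythms present in RE 3, the levels returned in RE 1 and the 12 h component in WT 13. With an amplitude of at least 0.25, rhythms were 1875 in WT, 2 in KO and 2290 in RE. With a level change of at least 0.5, level differences were 825 for KO against WT, 902 for RE against WT and 7 for RE against KO, with 3 returned and 708 shared. With only the genotypes compared, rhythms were 1 in KO and 3107 in RE, the 12 h component in WT 10, and RE against KO 2 in rhythm and 0 in level. Without the 2 libraries that stand apart, the RE against KO level difference was 79 and the levels returned 36. With list members scaled to unit SD, the xenobiotic level reversed to -0.040 for KO against WT (0.28) and -0.062 for RE against WT (0.23). Leaving out each library gave these ranges: rhythms in WT 3296 to 4045, in KO 0 to 161 and in RE 4486 to 5278. Rhythm differences ranged from 810 to 1148 for WT against KO, 1214 to 1769 for WT against RE and 145 to 687 for RE against KO. Level differences ranged from 4417 to 4786 for KO against WT, 4805 to 5234 for RE against WT and 13 to 172 for RE against KO. The rhythms present in RE ranged from 30 to 142, those lost from 232 to 306, the peak shift from 0.25 to 0.95 h and the log2 amplitude ratio from -0.04 to 0.08. Levels returned ranged from 6 to 66 and shared from 3669 to 3960. The 12 h component ranged from 16 to 50 in WT, 0 to 0 in KO and 0 to 1 in RE, with 1 without RE ZT8 liver 0 or RE ZT16 liver 1. The Bmal1 level ranged from 1.58 to 1.70 in KO and 1.49 to 1.61 in RE. Of the 283 results of named genes, 62 changed under at least 1 of 58 alternatives and 0 reversed; of the 297 results of lists, 71 changed under at least 1 of 59, and 2 reversed.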

Other observations

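The test of matching peak times used below was chosen after the values had been seen, as was the gene Alas2. The iron hormone Hamp was 3417 FPKM in WT, 1605 in KO and 1355 in RE (-1.39 log2 in KO against WT) and cycled in RE (1.34, SE 0.23, ZT10.8). The haem enzyme Alas1 cycled in WT (1.52, ZT12.9) and in RE (1.37, ZT13.7), and its red cell form Alas2 was lower in KO (-0.77). Alas2 belongs to the red cell list, whose mean was not called for KO against WT. Of the 6 tested genes of that list 1 was called lower in KO, against 1.21 expected. Uridine phosphorylase Upp2 was 183 FPKM in WT, 54.7 in KO and 47.6 in RE, and its rhythm in WT differed from both.

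Hypothesis: part of the RE rhythms follow a daily signal that also reaches KO livers, such as light or food, and that the central clock strengthens. Of 5116 RE rhythms, 51.9% had their KO peak within 3 h, against a permuted median of 23.6% (95th percentile 44.9%, 1-sided permutation p 0.0139), while 59.0% had their WT peak within 3 h and WT rhythms matched KO in 42.9%. If so, restricting food to a fixed time in KO mice might bring Angptl4, Pck1 and cholesterol synthesis genes near the RE peaks (ZT10.2, ZT12.5 and a list mean at ZT23.7). For Angptl4, Pck1 and the cholesterol synthesis mean, however, the rhythm difference from KO was larger than the RE amplitude. Their fitted KO peaks thus did not match the RE peaks, and they are no examples of a shared peak time. Since they were not called rhythmic in KO, those KO peaks are uncertain. Feeding times are not given in the sources used here, and KO mice in constant darkness would separate light from food.

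Hypothesis: glucocorticoid rhythm is one path from the central clock to the liver. The glucocorticoid list mean cycled in WT (0.55, ZT12.1) and in RE (0.78, ZT11.5) and differed from KO in both (0.79 and 0.99). Both differences were larger than the amplitudes in WT and RE, so part of each came from the KO livers. There the group mean ran from 4.83 at ZT0 to 4.12 at ZT16, though no rhythm of the list was called in KO. Over all genes, 2 of its 12 members were called in each of these differences. Large RE amplitudes in the list belonged to Angptl4, also in the PPAR alpha list, and to Mt1 and Mt2, whose RE calls ended with the RE libraries alone. The WT against RE difference of the mean was 0.25 (adjusted p 0.731 by limma), which does not show that they are equal. Per1, Fkbp5 and Tsc22d3 cycled in WT and in RE. Measured corticosterone over the day in the 3 genotypes, or adrenalectomy in RE mice, would test it; without a difference in corticosterone between RE and KO the hypothesis would fall.

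Hypothesis: the liver's own clock sets the peak time of some genes of fat metabolism against the central signal. In RE, Pdk4 peaked at ZT3.20 and Srebf1 at ZT22.4, against ZT21.8 and ZT12.3 in WT. Mice with Bmal1 in the liver and not in the suprachiasmatic nucleus, or in both, would separate the 2 clocks; a WT peak time in mice with both, and not in those with the central clock alone, would fit it.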
